A study of Mus musculus with 6 samples.

How the data were processed

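C2C12 cells, a mouse myoblast line that leaves the cell cycle and forms multinucleated muscle fibres when serum is lowered, were profiled on 6 arrays of the Affymetrix mouse whole-genome type named in the labels, a 1-colour array in which each transcript is read by a set of short probes. Growth medium held 10% fetal bovine serum, and differentiation medium, given once the culture was confluent, held 2% horse serum, per the labels' protocols. Parental cells were sampled in growth medium, at day 0 just after the change of medium, and at day 2 and day 4. A further pair of day 0 arrays came from stable transfectants, made with Lipofectamine 2000 and selected in G418 at 500 µg/ml for 2 weeks, per the labels. These transfectants carried either a short hairpin RNA against Rp58 (shRp58) or a control, which the labels describe both as a LacZ vector and as a control hairpin. The labels do not say whether the transfectants were pools or single clones, so differences between the lines could not be separated from differences between clones. Groups were taken from the sample titles. Each of the 6 groups held 1 array, so no replicate check and no p-value was possible, and the number of arrays limits the precision of every value.

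The deposited values are on the log2 scale and were made by the authors with the RMA algorithm from 10 ug of hybridised cRNA, per the series' design text. Software, versions and whether the arrays were normalized together are not given in the sources used here. The medians of all probe sets lay between 8.26 and 8.27 on the 4 time-course arrays and at 7.15 on both stable-transfectant arrays, so the deposited values form 2 sets with different scales. Differences were therefore read within a set. Values that cross the sets, such as control vector against parental cells, are given relative to the median of all genes, or, where this is said, after normalization of all arrays together or as deposited. They are given only as a description. The shift between the sets was not the same at all levels: the median of control vector minus parental day 0 ran from -0.84 in the lowest of 5 equal groups of probe sets by level to -1.22 in the next group and -0.95 in the highest.

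The table held 45101 probe sets. The platform annotation gave 1 gene for 34958 of them and several genes for 932, and 9211 had no gene there or were not listed. Only probe sets with 1 gene were named. Entrez gene IDs matched the RefSeq gene table of the GRCm38.p6 assembly for 34754 probe sets, and no symbol needed updating; that table was used for names only. Of several probe sets of a gene, the one with the highest mean over the 6 arrays stood for the gene, which gave 18194 genes, 9012 of them with at least 2 probe sets. A gene was kept when its highest value over the arrays reached 7.95, the median of all values, which left 13242 genes. No detection calls were used, so differences that start from or end at levels below 7.95 rest on dim probe sets, and their sizes and order are not exact.

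Differences are of log2 values between 2 arrays. Genes at least 2-fold apart were counted in each direction. The yardstick fixed for these counts was the control-vector array against the parental day 0 array, which differ in transfection and selection and not in day. Because these arrays also lie in different sets, that yardstick carries the shift between the sets, so only its counts relative to the median of all genes are set beside the others. Those counts still carry the part of the shift that varies with level. Robust standard deviations of differences over kept genes are scaled median absolute deviations. For 27 gene lists with 564 listed members, chosen for muscle, the cell cycle, signalling, stress and other cell types, the median difference of kept members is given with its percentile among 10000 lists of the same size drawn at random from genes of like level (20 bins of the mean). A 95% range from 2000 resamplings of the members describes the list and not replication. Correlations across genes compare the shRp58 difference with the time-course differences. Those differences share no array, and genes are not independent replicates.

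The genes named in the comparisons were set by rule: the 10 largest and 10 smallest differences for day 2 against day 0, day 4 against day 0 and shRp58 against control vector, the 5 largest and 5 smallest for the other 3 comparisons, the target gene, and any list member. Genes named outside this rule were chosen after their values were seen, as is said where they are given. A gene whose probe sets disagreed in sign past 2-fold is named with that fact. Groups, lists, comparisons, alternatives and this rule were fixed before the data were examined. While results were being checked, the matching of list members was corrected so that a current symbol is never read as another gene's older name; this removed Fbp1, Nckap1, Dmtf1 and Loxl3, which had been matched in error.

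Alternatives were no filter on low values, a filter at the 75th percentile, a filter on the mean, fold thresholds of 1.5 and 3, centring each array on its median, quantile and cyclic loess normalization of the 6 arrays, the mean of a gene's probe sets, leaving out probe sets whose names mark shared sequence, a floor at the 25th percentile, other baselines, and correlations without given lists. Parental day 0 as baseline after quantile or cyclic loess normalization, and the correlation without muscle and cell cycle lists, were added after seeing the data. Leaving out a replicate was not possible. The steps were tested on simulated differences for 13242 genes, drawn as independent normal noise. Its standard deviation was the robust one of shRp58 minus control vector, 0.17. Of 200 genes changed 3-fold or 4-fold, 100% passed the 2-fold threshold, of 200 changed 1.5-fold 0% did, and 0 unchanged genes passed. With noise this small those outcomes followed from the settings, so they check the code and not the rate of false calls in the real data. Of simulated lists of random genes with no shift, 6.33% fell outside the central 95% of random lists, which does not cover lists whose genes move together. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.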

Results

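The series follows mouse C2C12 myoblasts into muscle differentiation and sets cells that carry a hairpin against Rp58 beside control cells. Rp58, whose current symbol is Zbtb18, is a zinc finger protein that represses transcription, and the Id genes named below encode inhibitors of the myogenic helix-loop-helix factors. Each of the 6 groups was measured once: parental cells in growth medium and at days 0, 2 and 4 of differentiation, and stable control-vector and shRp58 cells at day 0. All differences are between single arrays and carry no replicate error, and none was tested. The array values of the stable lines lay about 1 log2 unit below those of the time course, so levels are not compared between those sets unless this is said.

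Zbtb18 was read by 1 probe set, at 11.18 log2 units in growth medium, 11.88 at day 0, 12.86 at day 2 and 13.06 at day 4. It was thus higher by 0.70 at day 0 than in growth medium, by 0.98 at day 2 than at day 0 and by 1.18 at day 4 than at day 0. In the stable lines it stood at 11.69 with the control vector and 11.16 with shRp58, a difference of -0.53. That difference had the sign the label of the hairpin array calls for, was 1.44-fold in size and did not reach 2-fold. The robust standard deviation of all genes between these 2 arrays was 0.17, which describes the spread across genes and not the error of this probe set. The central 95% of kept genes ran from -0.55 to 0.46 between these arrays, so the Zbtb18 difference lay inside that range. Against parental day 0 cells, after quantile normalization of the 6 arrays, Zbtb18 was not lower in shRp58 cells but 0.26 higher, and 0.72 higher in control-vector cells. Whether the probe set lies within the part of the transcript that the hairpin targets was not analysed here.

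**Figure D1:**
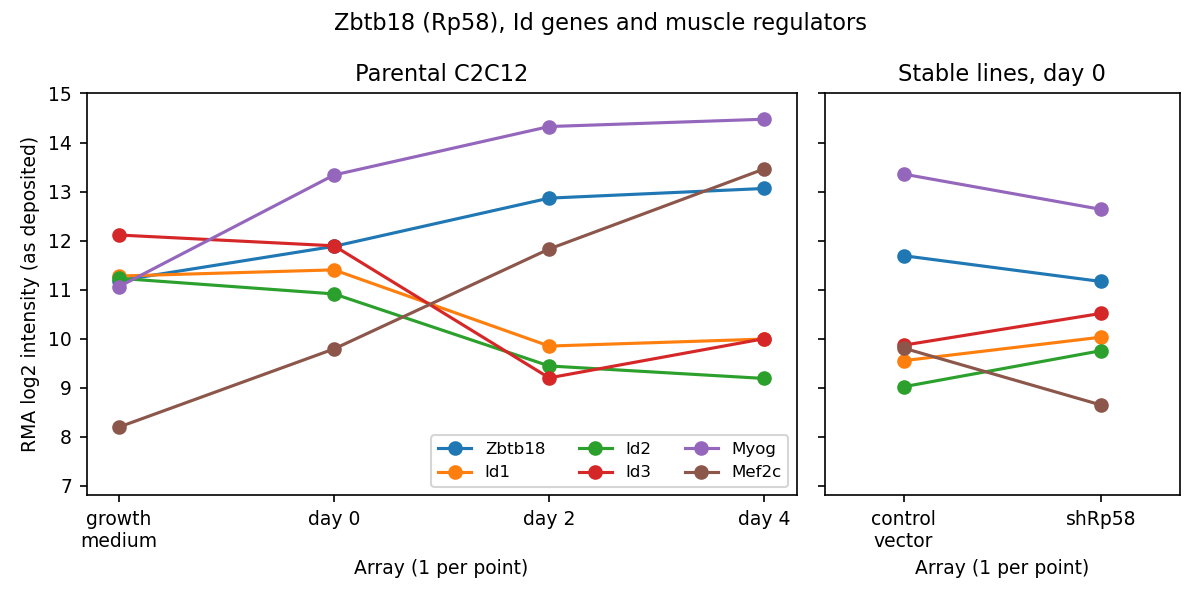
Log2 RMA intensity (y axis) of Zbtb18, Id1, Id2, Id3, Myog and Mef2c on each array (x axis), 1 array per point, with the parental time course on the left and the stable lines at day 0 on the right. Zbtb18 stood at 11.18 in growth medium, at 13.06 at day 4 and at 11.69 and 11.16 in control-vector and shRp58 cells; the 2 panels are on different scales of normalization, so levels are read within a panel.

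The comparison of day 0 with growth medium asks what differed once the culture was confluent and the medium had just been changed. Contractile genes were already higher at day 0. Myh3, the embryonic myosin heavy chain, stood 4.18 higher, and the fusion peptide gene Mymx 3.78, nebulin (Neb) 3.73, the fast troponin Tnnc2 3.54 and Klhl41 3.49 higher, where Mymx, Neb and Klhl41 read below 7.95 in growth medium. The genes furthest down were Ccnb1ip1 (-2.04), Serpinb2 (-2.03), the smooth muscle marker Tagln (-1.94), Epop (-1.68) and Cyp2c54 (-1.56), of which Ccnb1ip1, Serpinb2 and Epop read below 7.95 at day 0. Of 52 sarcomere genes, 29 were at least 2-fold higher and 0 lower, with a median of 1.31. The muscle regulator Myog was 2.28 higher and its partner Mef2c 1.59 higher, while Myod1 differed by 0.35.

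Other muscle groups were mostly higher at this step. Of 23 genes of excitation-contraction coupling 14 lay above 0 (median 0.52) and 9 were at least 2-fold higher, among them Srl (2.73), Atp2a1 (2.60) and Casq2 (2.43), but Casq1 differed by -0.88. For the neuromuscular junction 9 of 10 genes lay above 0 (median 0.48) and 3 were at least 2-fold higher, including the fetal acetylcholine receptor subunit Chrng (2.55). For fusion and surface proteins 18 of 20 lay above 0 (median 0.54) and 2 were past 2-fold, Mymk (2.68) and Tmem182 (2.505). Of 19 metabolism genes 15 lay above 0 (median 0.55), with Mb at 2.52 and Pdk4 at -1.14. Replication and mitosis genes were only slightly lower, with medians of -0.34 over 37 genes and -0.19 over 45 and none of them 2-fold apart. Id2, Id3 and Id1 differed by -0.32, -0.22 and 0.13, the last of these turning negative after centring, quantile and loess normalization. Matrix genes had a median of 0.31, with Col6a1 (1.49) and Col6a2 (1.41) highest, and 2 immediate-early genes, Egr3 (1.30) and Dusp6 (1.27), were past 2-fold. In all, 385 of 13242 kept genes were at least 2-fold higher and 42 lower, a share of 90.2% higher. That share was 65.8% after centring, 76.7% after quantile and 87.1% after loess normalization, and relative to the median difference of all genes, 0.098, the counts were 294 and 66. The sarcomere median relative to all genes was 1.21.

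From day 0 to day 2 the muscle programme was higher and the cell cycle programme lower. The ventricular and slow myosin light chain Myl2 stood 4.58 higher, followed by the muscle LIM protein Csrp3 (4.11), follistatin Fst (4.06), Myoz2 (3.65), Frmd4b (3.60), the fatty acid transporter Cd36 (3.51), the perinatal myosin Myh8 (3.50), Fgfbp1 (3.49), myoglobin Mb (3.36) and the calcium channel subunit Cacna1s (3.35). The genes furthest down were the neurofilament genes Nefl (-3.66, 12.6-fold) and Nefm (-3.27), the urea transporter Slc14a1 (-3.48), Igsf5 (-3.14), Fabp5 (-3.01), Krt19 (-3.00), the mitotic genes Melk (-2.93), Depdc1a (-2.89) and Kif20a (-2.82), and Gap43 (-2.81). Myl2, Frmd4b, Cd36, Myh8 and Fgfbp1 read below 7.95 at day 0, so the sizes and order of their differences are not exact. The same holds for genes that ended below 7.95 at day 2, among them Melk. Counts at 2-fold were 354 genes higher and 392 lower, a share of 47.5% higher that became 52.3% after centring, 53.8% after quantile and 56.2% after loess normalization, so which side held more genes depended on the scaling. The robust standard deviation of all differences was 0.32, against 0.35 for control vector minus parental cells at the same day, a comparison that crosses the sets of arrays.

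Of the 52 sarcomere genes 36 were at least 2-fold higher and 0 lower (median 1.66, 95% range over members 1.24 to 2.22), and of 19 muscle metabolism genes 12 were, led by Mb (3.36), Fabp3 (2.93) and the glycogen phosphorylase Pygm (2.60). Excitation-contraction genes had a median of 0.69 with 9 of 23 past 2-fold. All 45 mitosis genes were at least 2-fold lower (median -2.10), among them Cdc20 (-2.58) and Top2a (-2.14), as were 25 of 37 replication genes (median -1.39), among them Cdc6 (-2.69) and Mcm5 (-2.17). The 3 kept Id genes were all past 2-fold, Id3 by -2.69, Id1 by -1.56 and Id2 by -1.47, while Id4 was below the filter. Myogenic regulators had a median of 0.13, at percentile 97.85 of random lists, with members on both sides: Mef2c stood 2.04 higher and Smyd1 1.08 higher, Tcf3 differed by -1.10 and Vgll2 by -1.12, and Myog missed 2-fold at 0.99. The medians of the sarcomere and mitosis lists lay at percentiles 100 and 0 of random lists. For Tpm3 the brightest probe set gave -0.49 and others up to 1.62.

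Several groups outside muscle also stood apart at day 2. Interferon-induced genes had a median of 0.44, with Ifit1 (1.76), Irf9 (1.18), Oasl2, Ifit3 and Ifi27l2a at least 2-fold higher, 5 of 19. Cholesterol synthesis genes had a median of 0.36 with 14 of 17 above 0. Of 14 neuronal markers 7 were at least 2-fold lower, including Stmn2 (-2.54) and Tubb3 (-2.23). Notch genes had a median of -0.38, with Heyl at -1.39, Hey1 at -1.11 and Lfng at -1.01. Matrix genes had a median of 0.19 but spread widely, from Tnc at -2.15 to Postn at 2.99 and Dcn at 2.41. Among cell cycle exit genes Gadd45a stood 2.03 higher, Ccnd1 and Rbl1 differed by -1.52 and -1.36, and the inhibitor Cdkn1a by 0.73. Igf2 stood 1.92 higher.

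Day 4 extended the same picture. Myh8 stood 5.86 above day 0, the adult fast myosin Myh4 5.60, Myl2 5.26, Cd36 5.04, Hectd2os 4.996, Cilp 4.79, the slow myosin Myh7 4.63, Csrp3 4.59, the calcium store protein Casq1 4.45 and Tceal7 4.44. Of these, Myh8, Myh4, Myl2, Cd36, Hectd2os and Cilp read below 7.95 at day 0, so the sizes and order of their differences are not exact. The same holds for lower genes that ended below 7.95 at day 4, among them Bub1, Melk and Gsta2 named next. Nefl (-4.55, 23.5-fold) and Nefm (-3.83) were lowest, with Trip13 (-3.65), Bub1 (-3.63), Melk (-3.53), the glutathione transferase Gsta2 (-3.46), Slc14a1 (-3.42), Depdc1a (-3.36), Birc5 (-3.30) and Igsf5 (-3.27). Sarcomere genes at least 2-fold higher numbered 42 of 52 (median 2.17), excitation-contraction genes 15 of 23 (median 1.22), metabolism genes 11 of 19 (median 1.47) and neuromuscular junction genes 5 of 10 (median 1.01), with 0 lower in each of these lists. Of 20 fusion and surface genes 14 lay above 0 (median 0.32), with Cav3 4.01 and Tmem182 3.32 higher and Dock1 at -1.16. All 45 mitosis genes (median -2.57) and 30 of 37 replication genes (median -1.67) were at least 2-fold lower, and the Id genes stood at -1.90 (Id3), -1.73 (Id2) and -1.41 (Id1).

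Single regulators differed in course. Mef2c was 3.67 above day 0, Smyd1 1.88, Myf6 1.24 and Myog 1.14, whereas Myf5 was at -1.29 and Myod1 at 0.23. Cdkn1c stood 2.24 above day 0 and Igf1 2.75, with Igf2 at 2.33 and Igfbp2 at -2.38. Matrix genes went both ways, with Postn 4.32 and Dcn 3.04 higher and Tnc at -1.83, 8 of 38 being at least 2-fold higher and 4 lower. Notch genes had a median of -0.47, with 5 of 15 at least 2-fold lower, and neuronal markers a median of -1.03. Immediate-early genes had a median of -0.35, led by Fosl1 at -2.23. Counts at 2-fold were 507 higher and 750 lower, a share of 40.3% higher that became 53.4% after centring, 52.6% after loess and 47.0% after quantile normalization. The median of all genes was -0.04, and relative to it the sarcomere and mitosis medians were 2.21 and -2.53. Probe sets disagreed past 2-fold for Tpm3 (-0.66, others up to 3.41), Asph (-0.40, others from -1.11 to 2.46) and Cenpa (-3.21, another at 1.06).

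Between day 2 and day 4 fewer genes were 2-fold apart, 107 higher and 107 lower. The adhesion molecule Cd24a stood 3.67 higher at day 4, Myh4 3.28, the Wnt-binding protein Sfrp2 3.13, Bex1 3.02 and Serpinb9g 3.001. Gsta2 was lowest at -3.85, followed by the cytokine receptor subunit Csf2rb (-3.10), Cck (-2.93), Car8 (-2.90) and the quinone reductase Nqo1 (-2.61). Cd24a, Bex1 and Serpinb9g read below 7.95 at day 2 and the 5 lowest genes read below it at day 4, so the sizes and order of these differences are not exact. Muscle genes were again higher: 8 of 52 sarcomere genes were past 2-fold, with Myh8 (2.36) and Myot (2.15) after Myh4, as were 5 of 19 metabolism genes, led by Cox6a2 (2.47), and 2 each of the excitation-contraction (Casq1 and Atp2a1), fusion and surface (Cav3 and Tmem182) and regulator lists (Mef2c and Myf6). Interferon-induced genes were lower than at day 2 (median -0.57, 4 of 19 past 2-fold, Ifit1 at -1.68) and at day 4 stood near day 0 (median 0.00). Cholesterol genes were likewise below day 2, 16 of 17 of them (median -0.36). Unfolded protein and amino acid stress genes had a median of -0.19 with 11 of 18 below 0, although 3 of them, Trib3 (2.38), Chac1 (1.39) and Asns (1.28), were at least 2-fold higher. The share of genes higher was 50.0%, and 63.9% after centring, 51.1% after quantile and 56.1% after loess normalization. Mitosis and replication genes were lower by a further median of -0.46 and -0.27, and Id3 stood 0.80 higher.

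**Figure D2:**
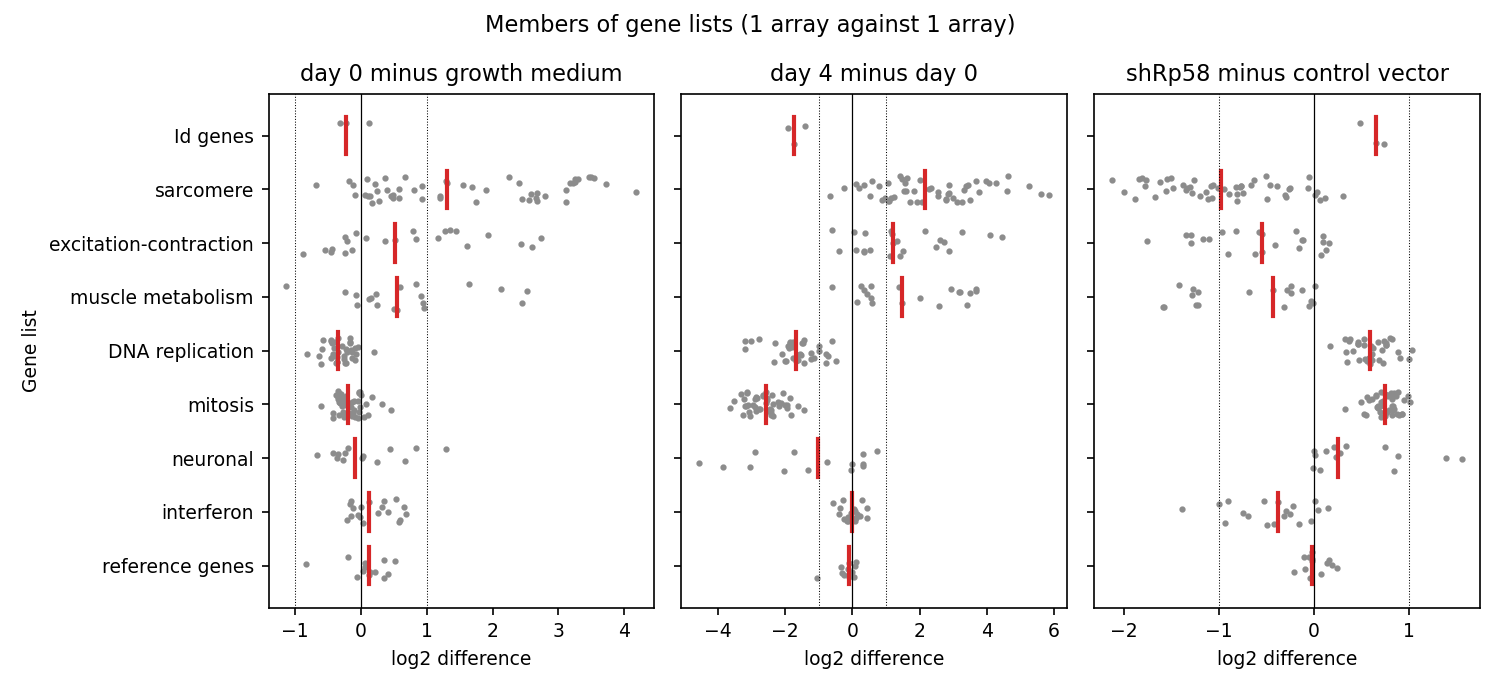
Log2 differences (x axis) of the kept members of 9 gene lists (y axis) for day 0 minus growth medium, day 4 minus day 0 and shRp58 minus control vector; grey points are genes, red bars are list medians and dotted lines mark 2-fold. Sarcomere medians were 1.31, 2.17 and -0.97 and mitosis medians -0.19, -2.57 and 0.75.

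The shRp58 comparison asks which genes differed between shRp58 and control-vector cells at day 0. With 1 array each it cannot show which of them depend on Rp58. Against the control vector, shRp58 cells had lower muscle genes and higher cell cycle genes at day 0. Myh8 stood at -2.12, Myh7 at -2.00, the actin-binding protein Ablim3 at -1.89, Csrp3 at -1.88, Myl2 at -1.84, Myl4 at -1.81, Fst at -1.79, Lmod2 at -1.77, Myh4 at -1.76 and Cacna1s at -1.76. Nefm (1.56), Nefl (1.39), Slc14a1 (1.19), thymidine kinase Tk1 (1.03), granzyme Gzmd (1.02), Shcbp1 (1.01), the mitotic kinesin Kif11 (1.01), Cdca5 (0.999), Cdc6 (0.998) and Melk (0.99) were highest. Myh8, Myh4 and Gzmd read below 7.95 on both arrays, and Myl2 did with shRp58, so the sizes and order of their differences are not exact. Only 7 genes were at least 2-fold higher and 82 lower. Relative to the median of all genes these counts were 9 and 81, against 224 and 221 for control vector minus parental cells, which carry no Rp58 hairpin. The latter counts cross the sets of arrays, whose shift varied with level, so they do not measure transfection and selection alone.

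Of 52 sarcomere genes 26 were at least 2-fold lower in shRp58 cells and 0 higher (median -0.97, 95% range over members -1.23 to -0.77). The same held for 8 of 19 metabolism genes, with Pygm at -1.59 and Mb at -1.57 (median -0.44), 6 of 23 excitation-contraction genes (median -0.55), 3 of 20 fusion and surface genes, with Tmem182 at -1.48, Cav3 at -1.21 and Mymk at -1.04 (median -0.27), and 2 of 10 junction genes, Lrp4 at -1.09 and Chrng at -1.02 (median -0.31). All 45 mitosis genes lay above 0 (median 0.75) and so did all 37 replication genes (median 0.59), although only Kif11 and Tk1 reached 2-fold. The 3 Id genes were higher by 0.48 (Id1), 0.74 (Id2) and 0.65 (Id3), none of them 2-fold, and their median of 0.65 lay at percentile 99.94 of random lists. Myogenic regulators had a median of -0.09 over 19 genes, with Mef2c at -1.16 and Myog at -0.72 but Myod1 at -0.13 and Myf5 at -0.07. Reference genes had a median of -0.02, which turned positive after each other normalization.

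In the lists outside muscle and the cell cycle few members were 2-fold apart. Interferon-induced genes were lower with shRp58 (median -0.37, 16 of 19 below 0, 1 of them past 2-fold), with Ifi27l2a at -1.39, Oasl2 at -0.999 and Ifit1 at -0.94. Smooth muscle markers had a median of -0.31, with Tagln at -0.84. BMP and TGF-beta genes were all 16 below 0 (median -0.23), Fst being the only one past 2-fold, and IGF genes had a median of -0.17 with Igf2 at -1.17. Matrix genes had a median of -0.14 with 0 of 38 past 2-fold, and adipocyte markers -0.22 with Cd36 at -1.50. Neuronal markers had a median of 0.25, cholesterol genes 0.24 and immediate-early genes 0.13, with Fos at 0.71. Medians were -0.13 for cell cycle exit, -0.12 for unfolded protein, -0.11 for quiescence, -0.06 for Notch, -0.06 for p53 target, 0.07 for osteoblast and 0.15 for leukocyte and endothelial genes, with 0 members of these lists 2-fold apart, and each of these medians lay within the central 95% of random lists.

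Gene by gene, the shRp58 difference ran opposite to the time course. Across 13242 genes it correlated with day 2 minus day 0 at Pearson r = -0.668 and Spearman rho = -0.446, and with day 4 minus day 0 at r = -0.637 and rho = -0.394. With day 0 minus growth medium it was r = -0.506 and rho = -0.467. Without the muscle and cell cycle lists, an alternative added after seeing the data, r was -0.605 for day 2 and -0.566 for day 4. Of the 82 genes lower with shRp58, 75 were among the 354 higher at day 2, where 2.19 would be shared by independent lists, and 77 were among the 507 higher at day 4, against 3.14. All 7 genes higher with shRp58, Nefm, Nefl, Slc14a1, Tk1, Gzmd, Shcbp1 and Kif11, were among those lower at day 2, and no gene was 2-fold apart in the same direction with shRp58 and at day 2 or day 4 against day 0. Slc14a1 was also 2-fold higher at day 0 than in growth medium (1.64). The 5 genes lower with shRp58 and not 2-fold higher at day 4 were Ptn (-1.59), Ifi27l2a (-1.39), the chemokine Cxcl12 (-1.19), Tmem47 (-1.07) and Plscr2 (-1.01). Of these, Ptn and Cxcl12 were 2-fold higher at day 0 than in growth medium (1.97 and 1.27) and Ifi27l2a was 2-fold higher at day 2 than at day 0. The 5 were singled out after their values were seen.

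**Figure D3:**
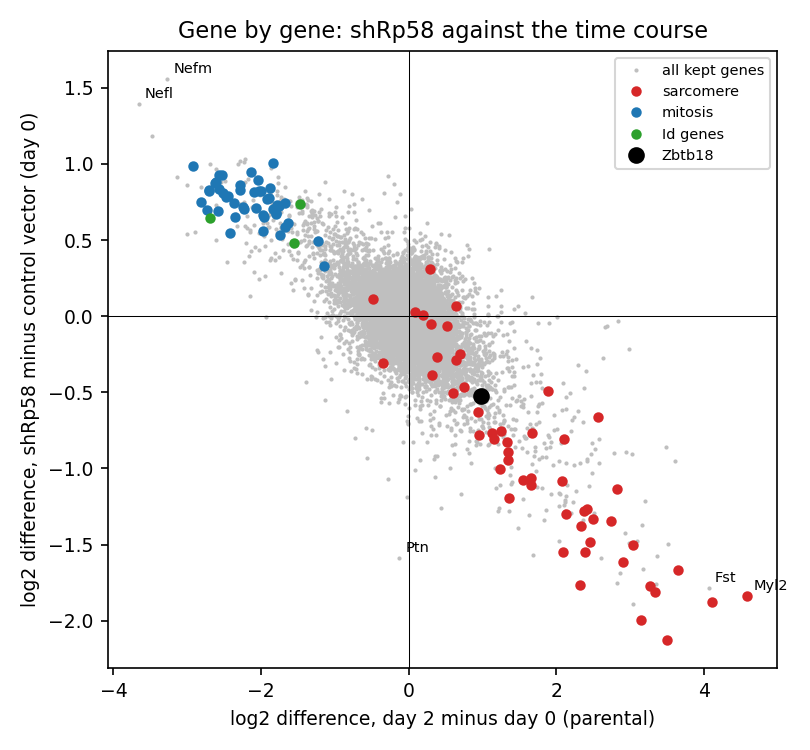
Log2 difference of shRp58 minus control vector at day 0 (y axis) against day 2 minus day 0 in parental cells (x axis), 1 point per kept gene, with sarcomere, mitosis and Id genes and Zbtb18 coloured. The points run from upper left to lower right (r = -0.668 over 13242 genes), with mitosis genes at upper left and sarcomere genes at lower right.

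The control-vector cells themselves stood apart from parental cells at day 0. Their deposited values were lower by a median of -1.02, so differences are given relative to that shift, and the arrays came from sets that look to have been normalized apart. Dcn (2.93), Myl4 (2.87), Phf11d (2.70), Ifit1 (2.69) and Gpnmb (2.57) were highest in control-vector cells, and Art3 (-2.58), Nefm (-2.45), Cdc6 (-2.34), Micall2 (-2.21) and Slc14a1 (-1.97) lowest. Relative to the shift, 31 of 52 sarcomere genes were at least 2-fold higher (median 1.32), excitation-contraction genes had a median of 1.05, mitosis genes -0.83, replication genes -0.63 and the Id genes -0.87, while Zbtb18 was at 0.83. Interferon-induced genes had a median of 0.94, and reference genes 0.38. Counts at 2-fold relative to the shift were 224 higher and 221 lower, while as deposited they were 25 and 6949, a share of 0.4% higher that became 51.8% after centring, 57.7% after quantile and 68.6% after loess normalization.

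**Figure D4:**
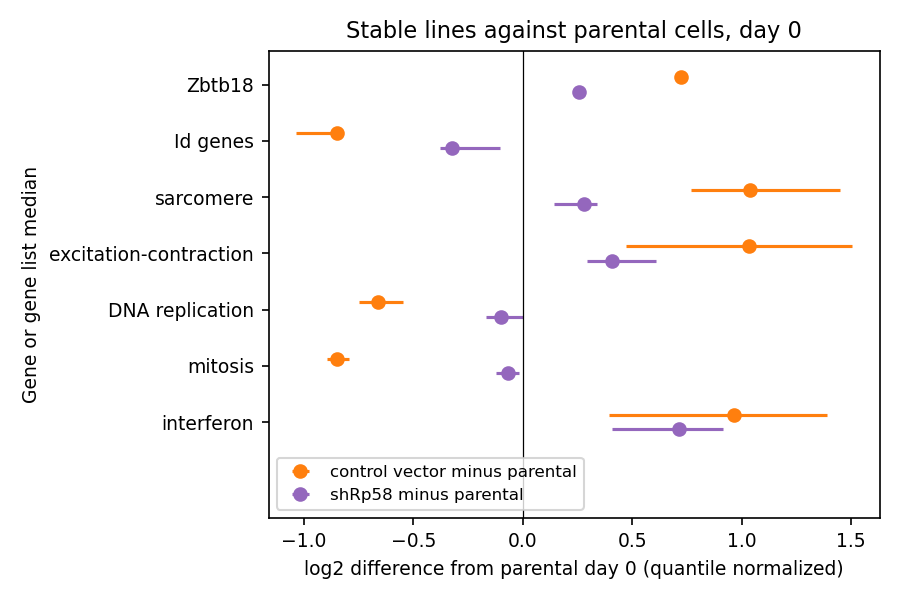
Log2 difference from parental day 0 after quantile normalization of the 6 arrays (x axis) for Zbtb18 and the medians of 6 gene lists (y axis), for control-vector and shRp58 cells; bars are 95% ranges over list members, and Zbtb18 is a single value. Control-vector cells lay further from parental cells than shRp58 cells for every item drawn, with sarcomere medians of 1.04 and 0.28 and Zbtb18 at 0.72 and 0.26.

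With parental day 0 as the baseline the shRp58 array looked different. After quantile normalization of the 6 arrays, Zbtb18 in shRp58 cells stood 0.26 above parental cells, the sarcomere median was 0.28, the mitosis median -0.07 and the Id median -0.32, and after loess normalization these were 0.29, 0.29, 0.02 and -0.24. The same quantities for control-vector cells after quantile normalization were 0.72, 1.04, -0.85 and -0.85. The lower muscle genes and higher Id and mitosis genes of shRp58 cells, and their lower Zbtb18, thus held against the control vector. After these normalizations they were not seen against parental cells, a comparison that crosses the sets of arrays and is a description only. Interferon-induced genes stood above parental cells in both lines, by a median of 0.96 with the control vector and 0.72 with shRp58.

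For the other lists the medians for day 2 and day 4 against day 0 were 0.12 and -0.03 for cell cycle exit, 0.24 and 0.06 for BMP and TGF-beta, 0.10 and 0.22 for IGF, 0.32 and 0.27 for p53 targets, with Eda2r at 2.91 at day 4, and 0.07 and 0.09 for unfolded protein genes. They were 0.24 and 0.23 for quiescence genes, 0.47 and -0.13 for adipocyte markers, of which Cd36 and Cebpd were 2-fold higher at both days, -0.04 and -0.01 for osteoblast, -0.17 and -0.03 for smooth muscle, 0.06 and 0.14 for leukocyte and endothelial and -0.09 and -0.10 for reference genes. Outside the central 95% of random lists, on the higher side, were BMP and TGF-beta (percentile 99.67), p53 target (99.83), quiescence (98.5) and adipocyte genes (99.87) at day 2 and p53 target (99.3), IGF (97.94) and quiescence genes (98.25) at day 4. Cell cycle exit, adipocyte, osteoblast, smooth muscle and reference medians changed sign at day 4 after centring. Of the leukocyte and endothelial markers 7 of 13 were below the filter on all arrays.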

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

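The alternatives were set before the data were examined, except for the parental day 0 baseline with quantile or loess normalization and the correlation without muscle and cell cycle lists, which were added after seeing the results. No paired analysis was possible because each group holds 1 array, leaving out a replicate was not possible, and the number of arrays limits the precision of every value. Of 144 counts under alternatives 98 stayed the same within the set tolerance and 46 moved. Of 1548 list medians 1325 stayed the same, 175 moved and 48 were counted as reversed. Not every list median that changed sign was counted as reversed. The cell cycle exit, adipocyte, osteoblast, smooth muscle and reference medians that changed sign at day 4 after centring were not. Of 1137 values of single genes 904 stayed, 190 moved and 43 were counted as reversed. Among single genes, only those at least 2-fold apart, and Zbtb18 in the day 2, day 4 and shRp58 comparisons, could be counted as reversed. A value of exactly 0 was counted as moved, a rule set after the results were seen that concerns Gzmd under the floor. Filters on low values leave a single gene's difference unchanged, so those alternatives could only stay the same. Of 26 correlations 22 stayed and 4 moved. Centring could not move them, and parental baselines were left out because they share an array with the time course.

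Counts followed the fold threshold. At 1.5-fold and at 3-fold the genes higher were 885 and 148 for day 2 against day 0, 1107 and 238 for day 4 against day 0, 347 and 34 for day 4 against day 2, 1443 and 97 for day 0 against growth medium, 189 and 0 for shRp58 against control vector and 68 and 4 for control vector against parental cells. The genes lower were, in the same order, 1105 and 157, 1852 and 286, 555 and 14, 389 and 4, 298 and 17, and 11769 and 1094.

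With growth medium as the baseline, genes 2-fold higher were 982 at day 2 and 1071 at day 4. The sarcomere median was then 3.26 at day 2 and 3.73 at day 4, the Id median -2.04 at day 4, Zbtb18 1.68 and 1.88, and the immediate-early median 0.17 at day 4, reversed in sign. The correlation of the shRp58 difference with day 4 was -0.765 on that baseline.

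Scaling moved the comparison of day 0 with growth medium: centring gave 221 genes higher and 115 lower, and quantile normalization gave 88 lower. The genes lower there were 24 under the stricter filter and 27 under the filter on the mean. For shRp58 against control vector centring gave 12 genes higher. For control vector against parental cells the genes higher and lower were 232 and 216 after centring, 211 and 155 after quantile and 264 and 121 after loess normalization; the mean of probe sets gave 16 higher and the stricter filter 4259 lower. Loess normalization gave an Id median of -1.44 at day 2. For control vector against parental cells, medians turned positive after centring, quantile and loess for neuromuscular junction (0.64, 0.54, 0.63), metabolism (0.48, 0.26, 0.34), interferon (0.95, 0.96, 1.03) and unfolded protein genes (0.34, 0.20, 0.28), as did metabolism under the stricter filter (0.054). The reversals after centring, quantile and loess go with removal of the shift of all genes between the 2 sets of arrays. For metabolism under the stricter filter, which leaves that shift in place, the cause was not tested.

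The mean of probe sets in place of the brightest gave mitosis medians of -1.83 at day 2, -2.15 at day 4 and 0.63 for shRp58 against control vector. The cause was not tested. The correlation with day 4 was -0.745 under the stricter filter. Among genes past 2-fold in the time course only, the correlations were -0.910 for day 2 and -0.866 for day 4. That choice leaves out genes with small time-course differences, which by itself makes a correlation larger in size, so these values do not show a stronger relation.

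The choice of baseline changed many shRp58 results. With parental day 0 as deposited, 3 genes were higher and 7058 lower, and medians were -1.37 for Id, -0.71 for sarcomere, -1.11 for replication, -1.06 for mitosis, -1.17 for cholesterol, -0.72 for immediate-early and -1.08 for neuronal genes. Single genes stood at -0.72 (Zbtb18), -1.91 (Nefm), -0.95 (Nefl), -1.81 (Slc14a1), -0.67 (Tk1), -1.80 (Gzmd), -1.33 (Shcbp1), -1.03 (Kif11) and 0.033 (Myl4). These values carry the shift between the sets. With the mean of the control-vector and parental arrays, 0 genes were higher and 364 lower, and medians were -0.37 for Id, -0.27 for replication, -0.15 for mitosis, -0.52 for cholesterol, -0.25 for immediate-early and -0.34 for neuronal genes. Nefm was then at -0.18, Slc14a1 at -0.31, Gzmd at -0.39, Shcbp1 at -0.16 and Kif11 at -0.011. The median of all genes on this mean baseline was -0.52, so these values also carry part of the shift. Apart from the cholesterol median they lay above that level, so their negative signs go with the shift.

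With parental day 0 after quantile normalization 52 genes were higher and 80 lower, and after loess 65 and 66. Although the counts of genes lower resemble the 82 against the control vector and fall among those that stayed the same, only 2 of those 82 genes, and 0 of the 7 higher, were shared under either. Medians after quantile and loess were -0.32 and -0.24 for Id, 0.28 and 0.29 for sarcomere, 0.41 and 0.45 for excitation-contraction, 0.20 and 0.25 for junction, 0.13 and 0.16 for fusion and surface, 0.067 and 0.11 for metabolism, -0.097 and -0.016 for replication, -0.068 and 0.015 for mitosis, 0.055 and 0.17 for IGF, -0.13 and -0.07 for cholesterol, and 0.72 and 0.74 for interferon-induced genes, with neuronal genes at -0.064 after quantile. Apart from the mitosis median after loess, each of these had the opposite sign to the control-vector baseline.

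Most single genes reversed in the same way. After quantile and loess normalization against parental day 0, Zbtb18 was at 0.26 and 0.29, Nefm at -0.87 and -0.77, Slc14a1 at -0.69 and -0.65, Gzmd at -0.62 and -0.53, Shcbp1 at -0.31 and -0.21, Myh7 at 0.57 and 0.58, Ablim3 at 0.15 and 0.12, Csrp3 at 0.64 and 0.65, Myl2 at 0.29 and 0.26, Myl4 at 1.03 and 1.001, Fst at 0.35 and 0.38, Lmod2 at 0.51 and 0.53, Myh4 at 0.30 and 0.28 and Cacna1s at 0.57 and 0.59. After quantile normalization Nefl was at -0.10 and Myh8 at 0.025. Of the 10 lowest genes against the control vector 10 had the opposite sign against parental day 0 after quantile and 9 after loess normalization, and of the 10 highest 7 and 5 did. Tk1, Kif11 and Melk kept their sign in both, though all 3 were far from 2-fold.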

Other observations

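The values against parental day 0 after quantile normalization were chosen only after the result was seen and are no tests. The tests that were kept were written down before their values were computed. The test of scaling was later limited to quantile and loess normalization because centring cannot move a correlation. Tests of a further stage of the control-vector culture and of an interferon response raised by the Rp58 hairpin were withdrawn after their results were seen. The interferon test restated the pattern it was to explain.

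The shRp58 difference ran opposite to the time course, and 2 explanations were tested. After quantile and loess normalization the weaker of the correlations with day 2 minus day 0 was -0.694, so the pattern did not depend on these. Arrays within a set already had like outer quartiles, for example 5.69 and 8.95 with the control vector and 5.73 and 8.91 with shRp58. The scaling test could thus hardly have come out otherwise, and it does not exclude other effects of scaling. Whether the control-vector culture was further along in differentiation stays open. The test of this was withdrawn, as it was written after its value was known. That value, the sarcomere median of shRp58 minus parental day 0, 0.28 after quantile normalization, also lies across the 2 sets of arrays. A difference in stage alone could also account for Zbtb18, whose residual after a fit on the time-course steps, -0.08, lay at percentile 22.4 of genes of the same level, so the lower Zbtb18 may be a cause or a consequence of stage. The same fit left median residuals near 0 for sarcomere (-0.004, -0.11 to 0.062), excitation-contraction (-0.038), junction (0.019) and metabolism genes (-0.045). These genes were part of the fit and had large time-course differences, so that follows in part from the fit itself. Median residuals were 0.19 (0.096 to 0.22) for replication, 0.099 (0.047 to 0.13) for mitosis, 0.20 (0.14 to 0.28) for cholesterol, -0.18 (-0.32 to -0.092) for BMP and TGF-beta and -0.24 (-1.05 to -0.026) for smooth muscle genes. Whether stage accounts for the whole pattern thus stays open.

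Interferon-induced genes stood lower with shRp58 than with the control vector. Stage alone may not suffice, since the median residual after the stage fit was -0.27 (-0.47 to -0.13). Both lines stood above parental cells, by 0.72 for shRp58 after quantile normalization, and a response to hairpins, transfection or selection stays open, since the labels do not make clear whether the control itself was a hairpin.

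Muscle genes were already higher at day 0 than in growth medium. A wider spread of the day 0 array is unlikely as the reason, because the sarcomere median after quantile normalization was 1.21 (0.65 to 2.41). Confluence before the change of medium may have started differentiation, which was not tested here.

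Some genes were chosen after their values were seen. No list was fixed for detoxifying genes known as Nfe2l2 targets, and their selection was not tested. Between day 2 and day 4, the genes picked were Gsta2 at -3.85, Nqo1 at -2.61, Gsta4 at -2.40, Aldh3a1 at -2.21, Srxn1 at -1.35, Gclm at -1.04, Gclc at -0.92, Txnrd1 at -0.83 and Hmox1 at -0.64. Gclc, Txnrd1 and Hmox1 did not reach 2-fold. Cth stood at 2.54 and Fgf21 at 2.42 in the same comparison, while the fixed list of unfolded protein and amino acid stress genes had a median of -0.19.

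The neurofilament genes Nefl and Nefm had among the largest differences in the series, -4.55 and -3.83 for day 4 against day 0 and 1.39 and 1.56 for shRp58 against control vector. In control-vector against parental cells they stood at -1.32 and -2.45 relative to all genes. They were chosen after their values were seen.

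The 3 prime hybridisation control BioC read 10.14 on the parental day 0 array and 8.79 on the control-vector array, while the 3 prime Cre control read 13.71 and 13.49. BioC had the widest gap of the BioB, BioC, BioDn and Cre controls. The 3 prime BioB and BioDn controls differed by only -0.38 and -0.41, less than the median of all genes, -1.02. The unequal gaps add to the reasons for reading levels within a set only.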
